A study of Homo sapiens with 12 samples.

How the data were processed

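N6-methyladenosine (m6A), a methyl mark on the adenosines of RNA, was mapped by methylated RNA immunoprecipitation sequencing (MeRIP-seq), in which RNA fragments are pulled down with an anti-m6A antibody and sequenced beside the input RNA. Per the labels, OVCAR-5 cells, an established ovarian cancer line, over-expressed either GFP or FTO-GFP. The 12 libraries formed 4 groups of 3 that the series' design text calls biological replicates: GFP input, FTO-GFP input, GFP m6A pull-down and FTO-GFP m6A pull-down. The titles of the 3 FTO-GFP inputs spell the construct with a different last letter; this was read as a typing error, since the design text names only GFP and FTO-GFP. Per the labels' protocols, pull-down used a commercial m6A kit with elution by free m6A, and libraries were made with an Illumina RNA kit.

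The submitters' processing notes list Trim Galore 0.4.4, cutadapt 1.14, STAR 2.5.2 and the genome build GRCh38, with no role or order. The peak caller, the gene annotation and the way replicates were combined are not given in the sources used here. The values analysed were the authors' own comparison, 1 deposited table of 22703 peaks under 11709 Ensembl gene identifiers, and a browser track of the same peaks that held nothing further. Per the file headers, each peak had a fold enrichment, a linear ratio of pull-down over input. It also had a log2 fold change of enrichment between conditions, as the authors deposited it. The authors gave a p-value and false discovery rate (FDR) for the peak and for the difference, the latter 4 as log10 scores; base 10 was read from the values, since for the 21876 peaks with a deposited p-value above 0 it equalled 10 to the power of its score within 0.02 log10 units. The number of blocks of each peak was read from the deposited table per the file headers. A Benjamini-Hochberg adjustment recomputed over the listed peaks gave the deposited FDR of the difference within 0.02 log10 units for 99.5% of peaks. The deposited FDR of the peaks themselves was 8.98 times that from the listed peaks alone (median), for a reason that was not tested. The largest peak FDR listed was 0.0479.

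The table held no value per library. No standard deviation, replicate comparison, leave-one-out fit or regrouping of samples was therefore computed, and the read depth behind each peak is unknown. The FDR of a difference is the authors' own, and it cannot be set here against the spread between the 3 replicates. The table does not state the direction of its fold change. It was taken as FTO-GFP over GFP, because the design text calls FTO-GFP the treatment and GFP the control; if it had been formed the other way, every "lower" below would read "higher".

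A peak was called different at a difference FDR below 0.05. For each identifier with several peaks, the gene value was the mean of their log2 fold changes. Gene symbols came from RefSeq GRCh38.p14, whose table used here held no Ensembl identifiers, so identifiers were named by position. An identifier took the symbol of the only RefSeq gene, of any kind, that met every one of its peaks within 100 nt, with peaks reaching at most 1000 nt outside it. Readthrough genes and symbols claimed by several identifiers were left out, and on the mitochondrial genome peaks had to lie within the gene. This named 8132 identifiers (69.5%) and 16469 peaks (72.5%). Of the rest, 485 identifiers met no gene, 2175 met several, 16 met only a readthrough gene and 901 shared a gene.

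Before the data were examined, 25 gene lists, the tests and the rule for named genes were fixed. The rule took the 8 called peaks of lowest and the 8 of highest log2 fold change with a symbol and a fold enrichment of at least 2. It added the 4 genes of smallest FDR in each direction; 7 genes tied at the smallest FDR among those lower, and the size of the change broke the tie. FTO was named in every case. Every called m6A writer, eraser, reader and cyclic nucleotide phosphodiesterase was named up to 8 per list, and up to 4 called members of each other list. The value of 1 gene that the rule takes is not reported here. The phosphodiesterase list was set knowing that the study takes an interest in these enzymes, so its result is not independent evidence. Genes named beyond the rule are marked as chosen after their values were seen.

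Lists were tested by two-sided Fisher's exact tests of genes with a called peak against the other named genes among 8132, with Benjamini-Hochberg adjustment over the 25 lists in each direction. The median gene value of a list was set against 10000 random lists matched on the number of peaks per gene. Further random lists were matched on each gene's strongest peak, the one of smallest peak p-value and not of largest fold enrichment. Genes and peaks are not replicates, so these tests describe the table. Within-gene differences by position used permutation tests with 100000 sign changes, and agreement of direction between peaks of a gene was set against 10000 shuffles. Shares carry 95% exact (Clopper-Pearson) binomial intervals over peaks or genes, which leave out the spread between cultures. A planned test of the DRACH motif and one of transcript regions (untranslated, coding, stop codon) were not run, since genome sequence and exon annotation were not used here. The region test was replaced by distance to the gene ends, at most 300 nt from the 5' end or 2000 nt from the 3' end, chosen after the data were seen.

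Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list tests were tested on simulated data over the 8132 named genes. Fold changes and FDR values were first shuffled over all peaks, which removes any link between calls and peak strength. Of 40 random lists of 30 genes, 0 were called by the count and 1 by the median. This does not show how often lists of genes with strong peaks would be called in the real table. All 10 lists in which 50% of peaks were set to a log2 value of -0.6 were called by both. Those peaks were also given an FDR below 0.05, so their recovery by the count was built in. The alternatives tried were stricter and looser FDR thresholds, a minimum fold change, filters on fold enrichment, peak FDR, blocks and peak length, centring on the median, genes as units, other gene summaries and another naming rule.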

Results

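m6A enrichment was measured in OVCAR-5 ovarian cancer cells that over-expressed FTO-GFP, a fusion of the RNA demethylase FTO with green fluorescent protein, or GFP alone. The comparison asked how RNA methylation differed between the 2 conditions, each with 3 pull-down and 3 input libraries. The authors' deposited table combined these 12 libraries into 22703 peaks under 11709 Ensembl genes, of which 6030 had 1 peak and 5679 had more, up to 22. Peaks had a median width of 240 nt (55 to 4201 nt), and 5851 of them (25.8%) spanned more than 1 block. Their median enrichment over input was 3.1-fold, with quartiles of 2.11 and 4.99 and extremes of 1.05 and 74.9. No value per library was in the table, so the values below carry the authors' false discovery rate (FDR) and no replicate error. How far that FDR reflects the spread between replicates is unknown, and so is depth.

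Most peaks that differed were lower in the FTO-GFP cells. At the FDR threshold of 0.05, 2399 peaks (10.6%) were called in the authors' deposited table, 2192 of them lower and 207 higher with FTO-GFP. The lower peaks made up 91.4% of those called (95% exact interval 90.2 to 92.5%). They lay in 1845 genes and the higher peaks in 180, with 31 genes holding both. The direction rests on reading the table's fold change as FTO-GFP over GFP, which the table does not state. Changes were small: the median log2 fold change was -0.42 among lower peaks, a fall of enrichment to 0.747 of its level in GFP cells, and 0.45 among higher peaks, a 1.37-fold rise. A change of at least 2-fold was called for 32 lower and 15 higher peaks, where 68.1% were lower, while 1843 peaks that were not called had changes of that size.

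The shift reached beyond the called peaks. Over all peaks the median log2 fold change in the authors' deposited table was -0.18 (quartiles -0.42 and 0.07), and 15580 peaks (68.6%) lay below 0. By gene, 8357 lay below 0 and 3250 above, a share of 72.0% (95% exact interval 71.2 to 72.8%; exact two-sided sign test over genes, p below 1e-300). All genes were measured in the same libraries, so this interval and p-value describe genes and not the spread between cultures. Peaks that were not called had a median of -0.15. Centring the table on its median moved every log2 value by 0.18, so a gene near -0.18 changed no more than the typical peak.

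The difference was larger at strongly enriched peaks. Over 5 equal groups of peaks, from the least to the most enriched, the median log2 fold change went from -0.077 through -0.12, -0.19 and -0.24 to -0.30. The least enriched group, with up to 1.95-fold enrichment, held 242 lower and 134 higher calls. The most enriched group, above 5.68-fold, held 669 lower and 2 higher calls. Median enrichment in the authors' deposited table was 4.21-fold for lower peaks, 1.71-fold for higher peaks and 3.03-fold for peaks that were not called. With peaks of at least 2-fold enrichment only, 1934 lower and 69 higher peaks were called.

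**Figure D1:**
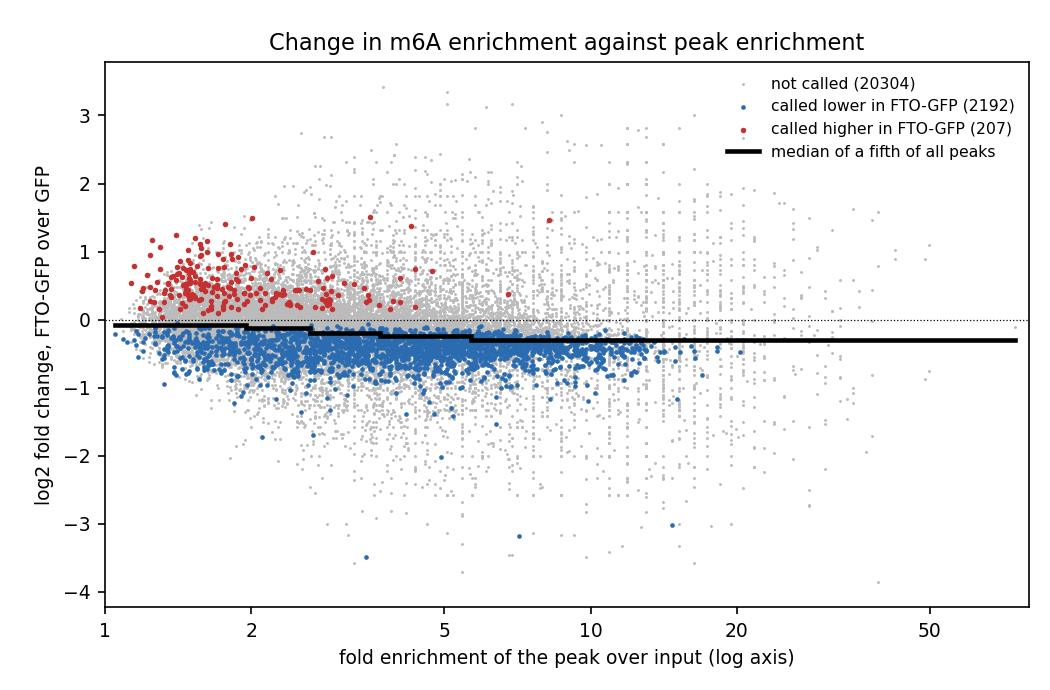
Log2 fold change of m6A enrichment, FTO-GFP over GFP, against fold enrichment of the peak over input (log axis) for 22703 peaks of the authors' deposited table, with the 2192 peaks called lower in blue, the 207 called higher in red and the median of each of 5 equal groups by enrichment as a black line. The medians go from -0.077 in the least enriched group to -0.30 in the most enriched.

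Among called peaks of named genes with at least 2-fold enrichment, the lowest log2 fold changes were at NATD1 and at TET1, which encodes a dioxygenase that oxidises 5-methylcytosine in DNA. In the authors' deposited table the NATD1 peak (ENSG00000274180, chromosome 17, 21242963 to 21243143) had a log2 fold change of -3.49, a residual 0.089 of the GFP level (FDR 0.00741). The TET1 peak (ENSG00000138336, chromosome 10, 68691516 to 68691756) had -3.18 (FDR 0.0269). The authors' deposited table next gave APC2, a relative of the WNT regulator APC, at -2.02, ABTB3 at -1.70 and the phospholipase C gene PLCH2 at -1.53. MED16, a subunit of the Mediator complex, stood at -1.39 in the authors' deposited table, ZNF827 at -1.38 and FAM13B at -1.36. Of these 8 peaks, those of NATD1 and APC2 (FDR 0.00955) passed an FDR of 0.01.

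Among called peaks under the same limits, the highest value was at IRX3, a homeobox gene that lies next to FTO and is controlled by enhancers in FTO introns. Its peak (ENSG00000177508, chromosome 16, 54286258 to 54286674) had a log2 fold change of 1.51 in the authors' deposited table, a 2.85-fold rise (FDR 0.0295). CALU, encoding the calcium-binding protein calumenin, followed at 1.49 with an FDR of 1.3e-09 in the authors' deposited table. The antisense RNA SPEN-AS1 had 1.46, the zinc finger gene ZNF100 1.37 and the paraspeckle gene PSPC1 1.00 (FDR 3.7e-04) in that table. CASP8, the initiator caspase of death receptors, had 0.75, the centrin gene CETN3 0.74 and the methionine salvage gene ENOPH1 0.72 in the authors' deposited table. CALU and PSPC1 alone among these 8 passed an FDR of 0.01. The smallest FDR values of higher peaks were at the ubiquitin gene UBB (0.79, FDR 7.9e-50), the ribosomal protein gene RPS3 (0.78, FDR 1.6e-30), the calmodulin gene CALM2 (0.38) and the DNA repair gene XRCC6 (0.34), all from the authors' deposited table. The UBB, RPS3 and XRCC6 peaks were less than 2-fold enriched, at 1.55, 1.15 and 1.80. Of the 143 named genes with a higher peak, 64 (44.8%) had a RefSeq pseudogene named after them, against 215 of 1361 genes (15.8%) with a lower peak (Fisher's exact test, two-sided, odds ratio 4.32, p = 1.9e-14).

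Mitochondrially encoded RNAs carried the smallest FDR values of the lower peaks. The complex I genes ND2, ND1 and ND6 and the complex III gene CYTB were at -0.30, -0.29, -0.26 and -0.25 in the authors' deposited table, each with a log10 FDR of -434, on peaks that were 5.10, 3.34, 9.10 and 4.49-fold enriched. In all, 7 genes tied at this smallest value, so it ranks none of them and may be a limit of the calculation. A value this extreme for falls this small cannot be read as a measure of agreement between the 3 replicates. All 13 mitochondrial mRNAs had a peak called lower, 14 of their 15 peaks in all, with a median log2 fold change of -0.25. The mitochondrial tRNAs were lower still, with 17 of 19 peaks called and a median of -0.50, from -0.055 at the aspartate tRNA TRND to -0.67 at the arginine tRNA TRNR. These tRNAs and the ribosomal RNAs were chosen for naming after their values were seen. The 4 peaks of the ribosomal RNAs RNR1 and RNR2 had a median of 0.021, 1 of them called lower and 2 higher. Of the 38 mitochondrial peaks, 29 began and ended exactly at the ends of a RefSeq gene, so most of these values describe whole transcripts. Nuclear peaks matched within 10% on fold enrichment had a median of -0.25 for the mRNA peaks, -0.21 for the tRNA peaks and -0.093 for the rRNA peaks.

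**Figure D2:**
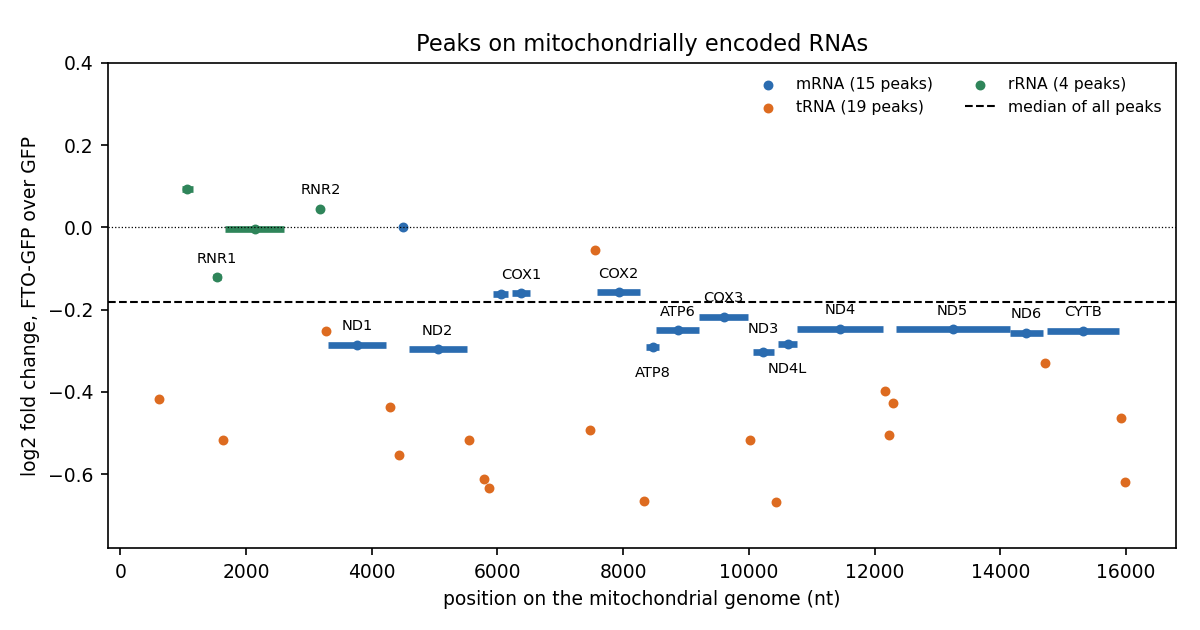
Log2 fold change of m6A enrichment, FTO-GFP over GFP, of the 38 peaks on the mitochondrial genome in the authors' deposited table, drawn at their positions in nt with lines for their extent; the dashed line is the median of all peaks (-0.18). The tRNA peaks (orange, median -0.50) lie below the mRNA peaks (blue, median -0.25), and the 4 rRNA peaks (green) lie between -0.12 and 0.095.

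Long non-coding RNAs were called less often than coding transcripts. Of 826 peaks in 525 named nuclear lncRNAs, 16 (1.94%) were called lower and 1 higher. Of 15280 peaks in 7352 nuclear coding genes, 1579 (10.3%) were called lower and 160 higher (Fisher's exact test of lower calls, two-sided, odds ratio 0.171, p = 1.6e-20). The median log2 fold changes were close, at -0.18 for both classes, and median enrichment was 4.49-fold in lncRNAs and 2.94-fold in coding genes. Values spread more widely in lncRNAs, with quartiles of -0.585 and 0.18 against -0.392 and 0.066 in coding genes. Read depth is unknown, so the lower rate of calls does not show that lncRNAs changed less. Peaks assigned to 219 pseudogenes had a median of -0.14, with 7 of 321 called lower.

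FTO (ENSG00000140718, chromosome 16) had 4 peaks, and none was called. Their log2 fold changes in the authors' deposited table were 0.0052, -0.23, -0.096 and 0.42 in order along the gene, with FDR values of 0.585, 0.0977, 0.56 and 0.731. The table gives enrichment over input and not the RNA level, so it does not check the over-expression. Among 8 measured m6A writers, the subunits and relatives of the methyltransferase complex, 3 had a peak called lower and none a higher one. They were ZC3H13 at -0.33 (FDR 2.3e-08), RBM15B at -0.69 and the cap methyltransferase PCIF1 at -0.51 in the authors' deposited table. Adjusted over the list alone, 4 writers had a lower peak. The count did not pass Fisher's exact test (adjusted p = 0.31). Of the 2 erasers measured, none had a called peak over all peaks, and both had a lower one when adjusted over the list alone.

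m6A readers, proteins that bind methylated RNA, carried lower peaks more often than the other named genes. Lower peaks were called in 7 of 13 measured readers (53.8%) against 16.7% of the other named genes (Fisher's exact test, adjusted p = 0.0152), and the count adjusted over the list alone was also 7. The authors' deposited table gave -0.28 for EIF3A (FDR 2.5e-35), a translation initiation factor, and -0.35 for PRRC2A (FDR 5.1e-10). The cytoplasmic YTH readers YTHDF1, YTHDF2 and YTHDF3 stood at -0.35, -0.24 and -0.44 in the authors' deposited table, the nuclear YTHDC1 at -0.79 and IGF2BP2 at -0.44. This YTHDC1 peak was 1.48-fold enriched, and a second called YTHDC1 peak, 5.41-fold enriched, was at -0.46. Higher peaks were called for HNRNPA2B1 (0.23, FDR 3.3e-10) and, chosen after its value was seen, HNRNPC (0.16) in the authors' deposited table. The list's median gene value, -0.17, was at the 47.1st percentile of random lists. Against lists matched on each gene's strongest peak, the count of lower genes did not pass (mean 5.96, permutation test, adjusted p = 1). Among readers with exactly 1 peak, 0 of 5 had a lower and 2 a higher peak. The latter count passed the test for higher peaks (Fisher's exact test, adjusted p = 0.0311). Those 2 peaks, of HNRNPA2B1 and HNRNPC, were only 1.93- and 1.43-fold enriched. With peaks of at least 2-fold enrichment only, 0 of 10 measured readers had a higher peak.

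Cyclic nucleotide phosphodiesterases, which break down cAMP and cGMP, had called peaks in 2 of 11 measured genes, close to the background share of 16.7% (18.2%, Fisher's exact test, adjusted p = 1). This list was set with knowledge of the study's interest and is not independent evidence. A PDE4B peak (ENSG00000184588, chromosome 1, 66368873 to 66373084, 869 nt in 2 blocks) was 11.7-fold enriched and fell by 0.28 on the log2 scale in the authors' deposited table (FDR 8.9e-08). The median of all peaks above 5.68-fold enrichment was -0.295, so this peak fell no more than the typical peak of that group. The PDE1C peak (chromosome 7, 31790083 to 31820615) stood at -0.44 in the authors' deposited table with an FDR of 0.0447. Adjusted over the list alone, 1 gene had a lower peak. Other genes of cAMP signalling had lower peaks in 7 of 23 genes and a higher peak in 1 (Fisher's exact test, adjusted p = 0.25 for lower), with the same counts adjusted over the list alone. The anchoring protein gene AKAP12 was at -0.33 and the stimulatory G protein gene GNAS at -0.32 in the authors' deposited table. The regulatory subunit genes of protein kinase A, PRKAR1B and PRKAR1A, were at -0.71 and 0.36 in that table. The GNAS and PRKAR1A peaks were only 1.11- and 1.36-fold enriched. With peaks of at least 2-fold enrichment only, 5 of 21 genes of this list had a lower peak and 0 a higher one.

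Immediate early genes, which respond first to growth signals, held the highest share of lower peaks among the 25 lists. Of 28 measured genes, 19 (67.9%) had a lower peak against 16.6% of the other genes (Fisher's exact test, odds ratio 10.6, adjusted p = 5.9e-08), and 20 when adjusted over the list alone. The authors' deposited table gave log2 fold changes of -0.36 for JUN (FDR 4.0e-23), -0.42 for EGR1, -0.43 for JUND and -0.27 for FOSB. JUN also had the list's 1 higher peak. The median gene value of the list was -0.20, against -0.16 in random lists of the same size (permutation test, adjusted p = 0.94). Against random lists matched on each gene's strongest peak, the count did not pass after adjustment (permutation test, adjusted p = 0.20).

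Chromatin regulators had lower peaks in 26 of 54 genes (48.1%, Fisher's exact test, odds ratio 4.69, adjusted p = 1.0e-06), 29 adjusted over the list alone, and no higher peak. The histone methyltransferase genes NSD1 and NSD2 were at -0.59 and -0.56 and the chromodomain remodeller genes CHD6 and CHD3 at -0.61 and -0.76 in the authors' deposited table. The median gene value was -0.26 (0.57th percentile of random lists, permutation test, adjusted p = 0.14). The list held 212 peaks, and the call ended among genes with exactly 1 peak (3 of 8, Fisher's exact test, adjusted p = 0.29). Against random lists matched on each gene's strongest peak, the count did not pass after adjustment over the 25 lists (permutation test, adjusted p = 0.14). TET1, named above, belongs to this list.

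Ribosomal protein genes had lower peaks in 13 of 28 measured genes (46.4%, Fisher's exact test, adjusted p = 0.0020) and higher peaks in 2, and 14 and 2 adjusted over the list alone. RPL13A, RPL36 and RPS24 stood at -0.31, -0.30 and -0.20 in the authors' deposited table, while RPS3 rose. Their median gene value was -0.084, at the 89.9th percentile of random lists. The call of this family ended among genes with exactly 1 peak (6 of 16, Fisher's exact test, adjusted p = 0.059). It also ended on the centred scale, where 7 genes kept a called peak below the median of all peaks (Fisher's exact test, adjusted p = 0.45) and 9 had a called peak above it, which is no test of a rise because the FDR remains that of a difference from 0. Transcripts reported elsewhere as FTO substrates had lower peaks in 8 of 19 genes (42.1%, Fisher's exact test, adjusted p = 0.0401), the same number adjusted over the list alone, where 1 gene also had a higher peak. The authors' deposited table gave -0.22 for JUNB, -0.19 for MYC, -0.089 for APOE and -0.52 for the retinoic acid receptor gene RARA. Their median was -0.11, at the 76.2nd percentile. This call ended on the centred scale (7 genes, Fisher's exact test, adjusted p = 0.15) and among genes with exactly 1 peak (1 of 9, adjusted p = 1). Against lists matched on each gene's strongest peak, neither the ribosomal protein count (mean 10.5) nor the FTO substrate count (mean 4.92) passed (permutation tests, adjusted p = 1 and 0.66). No list passed the test for higher peaks (Fisher's exact test, smallest adjusted p = 0.53).

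**Figure D3:**
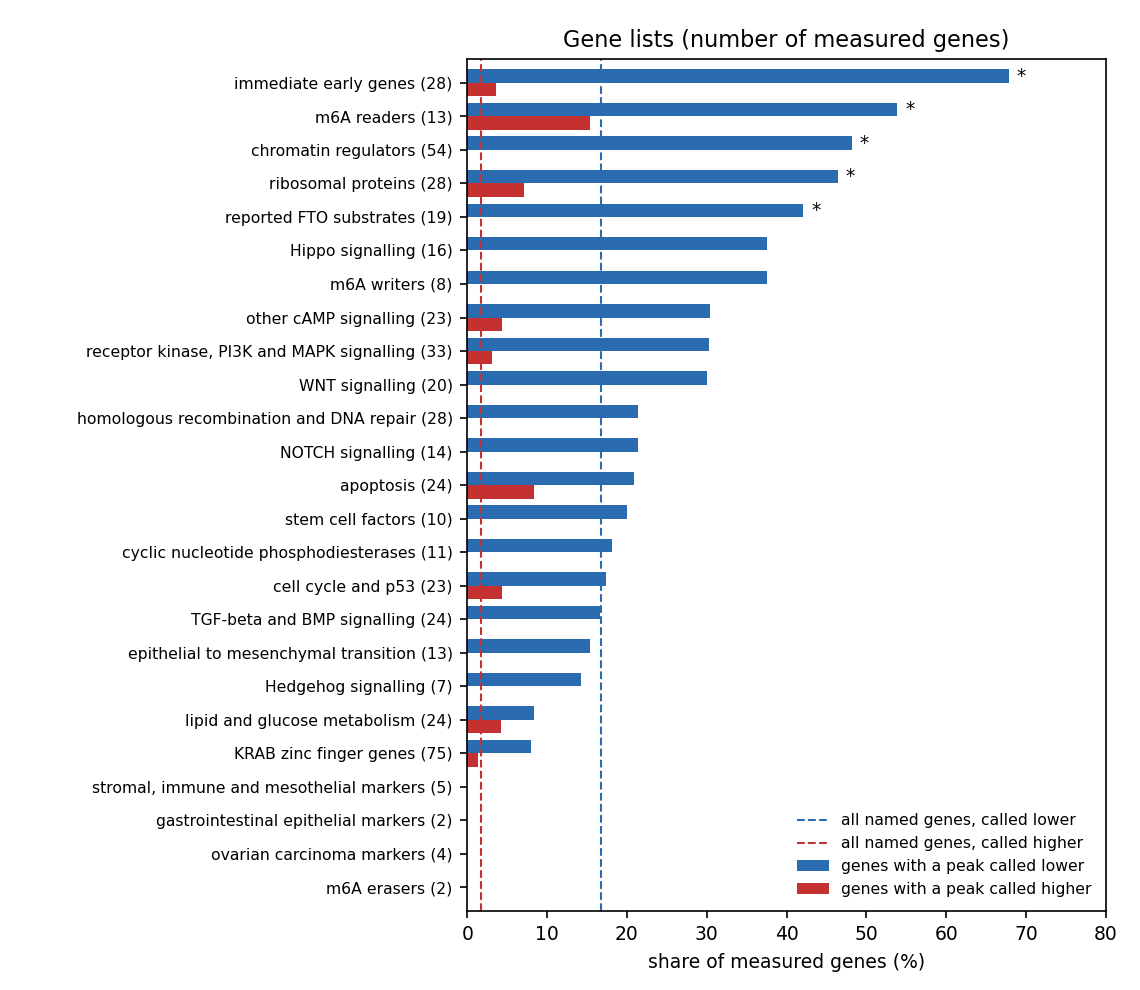
Share of measured genes, in %, with a peak called lower (blue bars) or higher (red bars) in FTO-GFP for each of the 25 gene lists, with the number of measured genes in brackets; dashed lines mark all 8132 named genes (16.7% lower, 1.76% higher) and asterisks the 5 lists that passed the test for lower peaks. Immediate early genes reach 67.9%.

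Signalling lists had lower peaks in some members without passing Fisher's exact test of the count. Hippo signalling had 6 of 16 genes (exact test, adjusted p = 0.15), with the transcription factor TEAD4 at -0.92 (FDR 5.1e-07), the kinase LATS2 at -0.52, AMOTL1 at -0.50 and CCN1 at -0.12 in the authors' deposited table. Receptor kinase, PI3K and MAPK signalling had 10 lower and 1 higher of 33 (exact test, adjusted p = 0.18), among them the feedback inhibitors SPRY2 (-0.54) and SPRED2 (-0.57), IRS1 (-0.33) and the mTORC1 subunit RPTOR (-0.71) in the authors' deposited table. WNT signalling had 6 of 20 (exact test, adjusted p = 0.31), with the co-receptor LRP5 at -0.43 (FDR 1.3e-11), BCL9L at -0.33, FZD6 at -0.36 and FZD7 at -0.42 in that table. NOTCH signalling had 3 of 14 (exact test, adjusted p = 1), among them NUMBL at -0.55 and MAML1 at -0.40 in the authors' deposited table. TGF-beta and BMP signalling had 4 of 24 (exact test, adjusted p = 1), with SMAD6 at -0.48 (FDR 1.8e-10), BMP4 at -0.38, the receptor ACVR1 at -0.86 and the BMP antagonist NOG at -0.36 in the authors' deposited table. Adjusted over the list alone, the lower counts were 6, 10, 8, 3 and 4 in the order given.

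Hedgehog signalling was the list whose median stood apart, at -0.73 over 7 genes against -0.18 for random lists (permutation test against random lists, adjusted p = 0.035 over 25 lists). Only SMO, the transducer of the pathway, was called, at -0.73 in the authors' deposited table (FDR 0.0309), and 1 gene was called adjusted over the list alone. The count of 1 of 7 genes did not pass Fisher's exact test (adjusted p = 1). Against random lists matched on each gene's strongest peak, the median did not pass (permutation test, adjusted p = 0.090).

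Proliferation, survival and repair lists had lower peaks at shares near the background. Cell cycle and p53 genes had 4 lower and 1 higher of 23 (Fisher's exact test, adjusted p = 1 for lower): MKI67 at -0.29, CDK6 at -0.66, E2F3 at -0.77 and the topoisomerase gene TOP2A at 0.51 in the authors' deposited table. Apoptosis genes had 5 lower and 2 higher of 24 (Fisher's exact test, adjusted p = 0.996 for lower). Their share with a higher peak was 8.33% against 1.74% of the other named genes, which did not pass (Fisher's exact test, adjusted p = 0.72). TNFRSF1A, TNFRSF10B and MCL1 were at -0.34, -0.50 and -0.15 in the authors' deposited table, and the cytochrome c gene CYCS at 0.35 (FDR 1.2e-08). The CYCS and TOP2A peaks were less than 2-fold enriched, at 1.70 and 1.63. With peaks of at least 2-fold enrichment only, 1 apoptosis gene and 0 cell cycle and p53 genes had a higher peak. Homologous recombination and DNA repair genes had 6 of 28 (exact test, adjusted p = 0.87), with CDK12 at -0.24, RNF168 at -0.56, the helicase gene BLM at -0.97 and XRCC2 at -0.41 in the authors' deposited table. Adjusted over the list alone, the lower counts of these lists were 4, 5 and 6, and the higher counts 1, 2 and 0.

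Cell identity and metabolic lists held few calls. Stem cell factors had 2 of 10 genes, MYC and KLF4 (-0.53), and genes of epithelial to mesenchymal transition 2 of 13, KRT18 (-0.23, FDR 1.0e-11) and DSP (-0.40), in the authors' deposited table (Fisher's exact test, adjusted p = 1 for both lists; 3 and 1 adjusted over the list alone). KRAB zinc finger genes had 6 lower and 1 higher of 75 (Fisher's exact test, adjusted p = 0.15 for lower; 2 and 0 adjusted over the list alone), with ZNF212 at -1.03, ZNF263 at -0.42 and ZNF274 at -0.48 in the authors' deposited table beside ZNF100. Lipid and glucose metabolism had 2 lower and 1 higher of 24 (Fisher's exact test, adjusted p = 0.86 for lower; the same counts adjusted over the list alone), SLC2A1, the glucose transporter gene, at -0.46 and PPARD at -0.92 in the authors' deposited table, with IRX3. None of the 4 ovarian carcinoma, 2 gastrointestinal and 5 stromal, immune and mesothelial markers measured had a called peak, over all peaks or adjusted over the list alone.

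Lower calls took a larger share near gene 3' ends. Positions were taken in named nuclear coding genes. Of called peaks within 2000 nt of the 3' end alone, 602 were lower and 29 higher (95.4% lower, Fisher's exact test against other positions, odds ratio 2.78, adjusted p = 1.0e-06). Within 300 nt of the 5' end alone, 110 were lower and 23 higher (82.7%, Fisher's exact test, odds ratio 0.446, adjusted p = 0.0034), and between the ends 848 and 107 (88.8%, odds ratio 0.575, adjusted p = 0.0030). The 80 peaks within both limits, 19 called lower and 1 higher, formed a class of their own. Of all peaks, lower calls made up 11.2% at 5' ends, 8.63% between and 13.7% at 3' ends, and higher calls 2.35%, 1.09% and 0.660%, so the smaller share of lower among the calls at 5' ends went with more frequent higher calls. The median log2 fold changes were -0.14 at 5' ends, -0.17 between and -0.20 at 3' ends, and median enrichment was 2.61, 2.92 and 3.07-fold. Within genes that had peaks at both places, no difference in mean log2 fold change was found over all peaks, called or not. The split of calls was not tested within genes. The mean of 5' minus 3' was 0.015 ± 0.037 (SE over 355 genes, permutation test, two-sided, p = 0.68). By the same permutation test it was 0.031 ± 0.025 for 5' minus between (544 genes, p = 0.22) and 0.019 ± 0.015 for 3' minus between (1530 genes, p = 0.22), none below 0.05 after adjustment over the 3 tests. With peaks of at least 2-fold enrichment only, the last 2 differences passed the permutation test without adjustment, at 0.073 (p = 0.030) and 0.049 (p = 0.020). Both were positive, so 3' peaks lay above those between, opposite to the order of the medians of all peaks above.

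Peaks of the same gene shared their direction slightly more often than shuffled peaks. Of 22016 pairs, 60.3% had the same sign, against a mean of 57.4% and a highest value of 58.9% in 10000 shuffles (permutation test, p = 1e-04, the smallest they can give). Among 521 pairs with both peaks called, 90.8% had the same sign against 81.6% in shuffles (permutation test, p = 1e-04).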

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

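The alternatives with mitochondrial peaks left out, with enrichment below 2, with distances to gene ends, with genes named by coding genes alone and with signs against the median were chosen after the data were seen. No paired analysis was possible because the deposited table has no value per library, and leaving out replicates was not run for the same reason. The planned motif and transcript-region tests were not run. Lower peaks outnumbered higher ones under all 10 alternatives to the peak counts, with shares from 65.2% (enrichment below 2) to 96.6% (at least 2). Counts moved most with an FDR of 0.01 (1293 lower, 120 higher), with a log2 change of at least 1 (32 and 15) and with enrichment of at least 2 (69 higher) or below 2 (258 lower). Fewer peaks can pass each of these by construction. Centring, which moved every value by 0.18 and kept the FDR of a difference from 0, gave 2095 lower and 303 higher. The median gene value stayed between -0.21 and -0.18.

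The 5 lists called lower became 1 with genes of 1 peak (immediate early genes), 0 with a log2 change of at least 1 and 3 after centring, which ended the calls of ribosomal proteins and reported FTO substrates. The 0 called higher became 1 with genes of 1 peak (m6A readers, on peaks less than 2-fold enriched). After centring it became 3 (readers, immediate early genes, ribosomal proteins). The last count is no test of a rise, since small falls with a low FDR turn to higher calls under the uniform shift by construction. With genes of 1 peak, the 1 list with a distinct median (Hedgehog) became 0, its median being -1.15 over the 3 genes left (permutation test, adjusted p = 0.21). By position, 5' minus between became 0.073 and 3' minus between 0.049 with enrichment of at least 2, and 5' minus 3' reversed to -0.026 in peaks up to the median length; the cause was not tested. Of 96 called peaks named, centring kept the sign of 93 and reversed CCN1 (0.066), MCL1 (0.032) and APOE (0.092), whose falls were smaller than the median shift. An FDR of 0.01 ended 27 of these calls, and 16 had enrichment below 2. Agreement between peaks of a gene held under its 3 alternatives. The depth of each library is unknown, and so is what it limits.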

Other observations

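The tests in the first 3 paragraphs below, on genes with peaks in both directions, on the Hedgehog list and on the direction of all peaks, were chosen after the results were seen, while those of the weakly enriched higher peaks and of list counts against peak strength were written before their results. Some genes had called peaks in both directions. There were 21 named ones, and in 20 every higher peak was less enriched over input than every lower peak (medians of 1.73 and 3.05-fold). In the translocation gene SEC62, the authors' deposited table gave 1.20 at 1.53-fold enrichment (chromosome 3, 169966814 to 169968490) and -0.30 at 10.9-fold enrichment (169985157 to 169993288). In the proteasome gene PSMD2 it gave -0.51 (FDR 1.3e-30) and 0.37 for neighbouring peaks, and in the developmental gene CRIM1 -0.30 and 1.41. JUN had -0.36 and -0.14 at its more enriched peaks and 0.68 at a 1.86-fold enriched one in the authors' deposited table. The amyloid precursor gene APP and the chaperone genes HSPA8 and HSP90AA1 were also among the 21.

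The median of the Hedgehog list rested on few measurements. Its 7 gene values were -1.81 for the ligand gene IHH, -1.15 for CDON, -0.92 for GAS1, -0.73 for SMO, -0.47 for SUFU, -0.078 for GLI2 and -0.050 for GLI3, all from the authors' deposited table. Leaving out each gene in turn gave medians from -0.82 to -0.60. Against random lists matched on each gene's strongest peak, the median was at the 0.16th percentile (permutation test, adjusted p = 0.090).

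Most peaks were lower in FTO-GFP, and a single scaling factor for all peaks would move weakly and strongly enriched peaks alike. The most enriched of 5 equal groups lay -0.22 from the least enriched on the log2 scale (95% bootstrap interval over genes -0.23 to -0.20), which argues against it. A loss of m6A in nuclear-encoded transcripts alone would leave mitochondrial mRNAs near 0, but their median was -0.25. A weaker pull-down over background in the FTO-GFP libraries is consistent with these mRNAs, whose peaks differed from nuclear peaks of matched enrichment by a median of -0.045 (interval -0.084 to 0.0070), but it falls short for the mitochondrial tRNAs, which lay -0.26 from theirs (interval -0.40 to -0.20), and -0.36 from matched nuclear peaks of at most 100 nt, while the 4 rRNA peaks lay 0.14 above theirs, too few for a test. Demethylation by the over-expressed FTO, which the design names, stays open beside the weaker pull-down, since spike-in or per-library values were not analysed here.

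Peaks called higher were weakly enriched over input, and reads shared with processed pseudogenes were weighed because these genes often have one. Among genes without a pseudogene of their name, the median enrichment of higher peaks was still 0.406 of that of lower peaks (interval 0.377 to 0.435; 86 and 1374 peaks), which argues against shared reads as the whole cause. A detection limit of the difference test was to be judged by whether uncalled peaks above and below 0 were equally enriched; the ratio of their medians was 0.860 (interval 0.843 to 0.881), but the fall of the median with enrichment already puts it below 1, so this decides nothing. The detection limit, gains of background signal in the FTO-GFP pull-down and real gains of m6A stay open, the last 2 untested.

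Gene lists with many lower calls may owe them to strong peaks, since strong peaks may be called more easily. Easier calling was not tested apart from the larger shift at strongly enriched peaks. Random lists matched on each gene's strongest peak had a mean of 10.5 genes with a lower peak for ribosomal proteins (13 observed), 5.96 for m6A readers (7 observed) and 4.92 for the reported FTO substrates (8 observed), so peak strength is consistent with these 3 counts. For immediate early genes the matched mean was 13.6 (central 95% from 10 to 18) against 19, and for chromatin regulators 17.3 (11 to 23) against 26. Both counts lay above the central 95%, the outcome set beforehand as speaking against strength as the whole cause. Adjusted over the 25 lists, however, these excesses had permutation p = 0.20 and p = 0.14 and did not pass, so strength stays open for both counts. The lists' median log2 fold changes, -0.20 and -0.26, were at the 55.0th and 2.73rd percentiles of the matched lists (permutation tests, adjusted p = 0.94 and 0.46). The hypothesis that FTO acts on these groups by preference was not tested further.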
